A study of Drosophila melanogaster with 2 samples.

How the data were processed

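Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole Drosophila melanogaster embryos of both sexes, 0 to 24 h old, per the labels. The embryos came from a transgenic line that stably carries CHES-1-like fused to GFP, per the labels. An antibody against GFP was used, and chromatin was sonicated to fragments of 200 to 800 bp, per the labels. The 2 samples are biological replicates 2 and 3 of 1 group, each with technical replicate 1, and come from separate biosamples of the same line. No second condition exists, so the comparisons are between replicates, between peaks and other parts of the genome, and between gene groups. No p-value was computed across the 2 samples. A control library entered the lists upstream, per the deposited file manifests, and is not analysed here.

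Each list holds 1 line per summit, here called a peak, with a signal value, which is the authors' own, deposited on the scale of its own list. It was used only to describe, rank and filter peaks within a list. The deposited −log10 of the q-value and the position of the summit were read from the same lines. A region with more than 1 summit stands on more than 1 line, with 4 such repeats in the thresholded and 9 in the pooled dm6 list. Per the deposited manifests, each replicate list was derived from the alignments of that library and the control, the pooled list from the alignments of both libraries and the control, and the thresholded list from both replicate lists and the pooled list by the irreproducible discovery rate procedure. The replicate and pooled lists are described there as peaks and background, and each holds 30000 entries. Aligner, peak caller, their versions and the irreproducible discovery rate limit are not given in the sources used here. The files give no read counts, so the depth is unknown, and every interval below covers counting error over peaks or genes only. Neighbouring peaks and genes are not independent replicates, so p-values over them describe these lists.

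Lists exist on the dm6 and dm3 assemblies. Locations, genes and sequences were taken on dm6 from release 6 of the genome and Ensembl annotation release 115. Every dm6 peak lay within the reference arm lengths, and on arm 3R the last dm6 peak ended at 32068709 of 32079331 bp. Coordinates were not converted between assemblies. Protein-coding genes on arms 2L, 2R, 3L, 3R, 4, X and Y were used, 13968 genes with 19630 distinct transcription start sites (TSSs).

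Peaks of different lists were matched when their summits lay within 100 bp. Replicates were compared over their 4599 best peaks by signal, the size of the thresholded list, against 100 random rotations of 1 list along each arm. Summits were classed in the order promoter (within 500 bp of a TSS), 5' UTR, coding sequence, 3' UTR, intron, other exon and intergenic, and set against the sub-threshold peaks of the pooled list with Fisher's exact test and against 100000 random positions, of which 99617 fell on known bases. A gene was called bound when a thresholded summit lay within 500 bp of any of its TSSs. For 31 gene lists, bound members were set against all other protein-coding genes with Fisher's exact test. For 12 motifs, windows of 100 bp on each side of the summit were set against windows centred 1000 bp away with the exact McNemar test. Among these motifs are a forkhead site, a GACGC site, and both sequences reversed without complementing, as controls of equal base composition. Arms were tested with an exact binomial test. All tests were two-sided unless stated, p-values were adjusted by the Benjamini-Hochberg method within each family at 0.05, and shares carry exact Clopper-Pearson intervals at 95%.

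The tests, gene lists, motifs and the rule for named genes were fixed before the data were examined. Older gene symbols were matched to current ones, and genes of other families caught by name patterns were removed from the lists, after the files had been opened and before any list was tested. The named genes are CHES-1-like itself, the gene with the nearest TSS to each of the 20 strongest thresholded peaks, up to 4 members of each list with the strongest thresholded peak at a TSS, and polo, fz, fz2 and jumu. Alternatives covered the matching rule, the number of peaks, the TSS window, 1 TSS per gene, a stricter threshold, either replicate alone, other gene backgrounds and other motif controls. Another 4 alternatives were chosen after seeing the data.

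The statistics were tested on simulated data. With 4000 simulated peaks a planted motif was called and 0 of 11 others were. With 13968 genes, 8 of 8 changed lists and 0 of 23 unchanged lists were called. The simulated lists were larger than most lists tested here, and their planted differences in bound share were large. Smaller lists or differences may thus be missed. An overlap simulated at 60.9% of 4000 peaks was recovered as 61.1%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.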

Results

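Binding of CHES-1-like, a Drosophila transcription factor with a forkhead DNA-binding domain, was mapped by ChIP-seq for its GFP fusion in whole embryos aged 0 to 24 h, in 2 biological replicates of 1 group. The thresholded dm6 list held 4599 peaks, which were exactly the 4599 strongest of the 30000 entries in the pooled list. Their signal, the authors' own value, ran from 84.2 to 2442 with a median of 130, against a median of 37.2 over the whole pooled list. The 2 replicate lists held 30000 entries each, of which 9439 in replicate 2 and 7650 in replicate 3 had a deposited q-value under 0.05.

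The tagged gene itself was among the loci with the strongest peaks. CHES-1-like (FBgn0029504; X, 7682338 to 7709385 in dm6, minus strand) held 14 thresholded summits, 3 at promoters and 11 in introns, and none in its coding sequence. Its strongest peak, at 7708937 to 7709172, had its summit 266 bp from a TSS and a signal of 682, and ranked 63 among the thresholded peaks. The matching peak ranked 42 in replicate 2 and 98 in replicate 3. The next in strength lay in introns or at the inner TSSs, with summits at 7700413 (signal 627), 7697086 (587) and 7698433 (547).

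**Figure D1:**
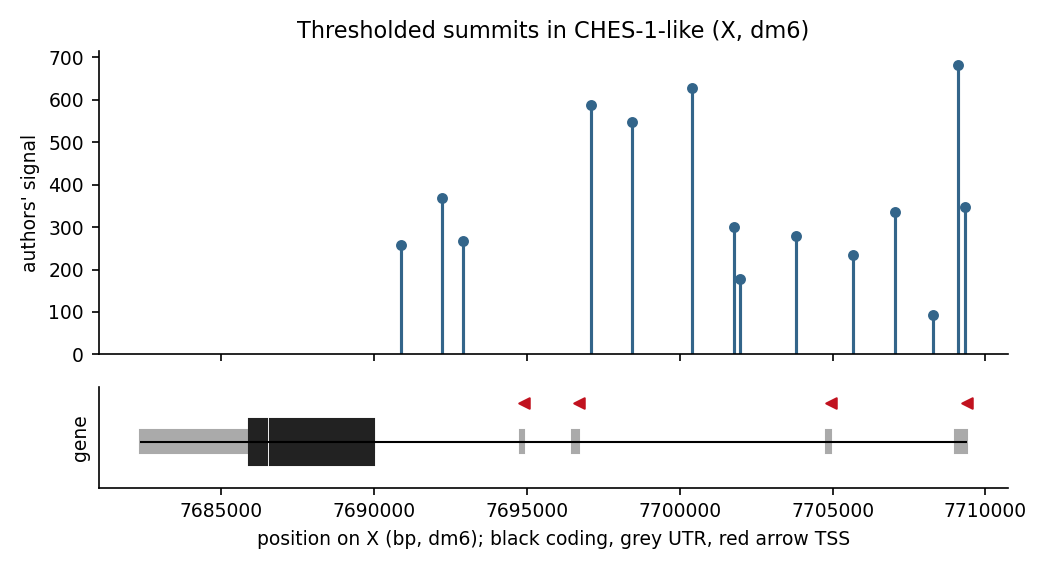
Thresholded summits in CHES-1-like by position on X (bp, dm6), with the authors' signal as height above and the gene model (coding sequence black, UTR grey, TSSs red) below. The 14 summits lie between 7690877 and 7709320, outside the coding exons.

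Named genes of heart development and cell division differed in where their peaks lay. polo, which encodes a mitotic kinase, had 1 thresholded peak, 66 bp from a TSS, with rank 2187. It ranked 1910 in replicate 2 and 2273 in replicate 3. fz, a Wnt receptor gene, had no thresholded summit at its TSS, where the best pooled peak ranked 6627, but 3 within the gene, the best with rank 269. jumu, another forkhead gene, had no thresholded summit at its TSS and 4 within the gene, the best with rank 1506. fz2, a second Wnt receptor gene, had no thresholded summit at a TSS or in the gene, and its best pooled peak ranked 4729.

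The replicates shared their strongest sites. The strongest peak of all, at 2L 480841 to 481322, ranked 1 in both replicates, and the peaks at CG14100, Ugalt and px held ranks 2, 3 and 4 in both. Of the 4599 best peaks of replicate 2, 3170 (68.9%, 95% interval 67.6 to 70.3) had a summit among the 4599 best of replicate 3 within 100 bp, against a mean of 0.692% and a maximum of 1.09% in 100 rotations. The matched share fell with strength. In replicate 2 it was 98.2% (97.1 to 98.9) of the 920 strongest and 34.8% (31.7 to 38.0) of the 919 weakest peaks. In replicate 3 it fell from 97.7% to 33.1%. Both lists were cut at 4599 peaks, so a peak near the cut matched only if its counterpart ranked above the cut too. This lowers the share among the weakest by construction. Of the thresholded peaks, 4322 (94.0%, 93.3 to 94.6) were found in both whole replicate lists, 161 in replicate 2 alone, 113 in replicate 3 alone and 3 in neither. The thresholded list was derived from both replicate lists, so this share is high by construction. Only 3191 (69.4%) ranked among the 4599 best of both. Across the 4322 peaks found in both, ranks correlated with a Spearman rho of 0.702. This is a value across peaks, which are not independent replicates.

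**Figure D2:**
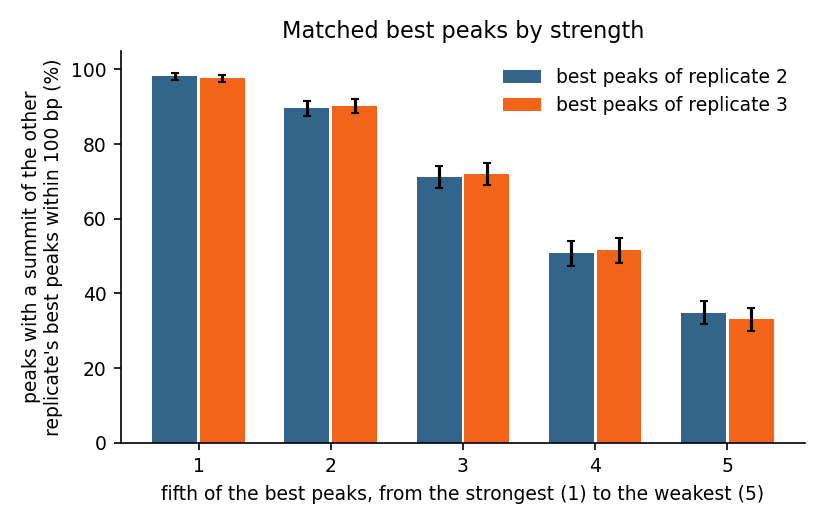
Percent of each replicate's 4599 best peaks with a summit of the other replicate's best peaks within 100 bp, in 5 groups from the strongest to the weakest, with exact 95% intervals. In replicate 2 the share falls from 98.2% to 34.8%, and in replicate 3 from 97.7% to 33.1%.

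The strongest peaks lay mostly at promoters of genes with varied roles. The top peak (signal 2442) lay in an intron of ush, whose product is a partner of GATA factors, 1378 bp from the TSS of cbt, a zinc finger transcription factor gene. It was followed by peaks at the promoters of CG14100 (signal 1958, 97 bp from a TSS), Ugalt, a UDP-galactose transporter gene (1873, 51 bp), and px, named for its wing vein phenotype (1656, 195 bp). Lk6, a protein kinase gene, had an intronic peak 972 bp from a TSS with signal 1590, and CG11050 one at 1033 bp with signal 1560. Promoter peaks also stood at mRpL41 (1346), CG1888 (1327), larp, an RNA-binding protein gene (1280), ph-p, a Polycomb group gene (1246), PNPase (1215), Art3, an arginine methyltransferase gene (1212), Chro, a chromatin and spindle protein gene (1185), Shc, an adaptor protein gene (1134), Pal1 (1129) and CG31145 (1090). Intronic peaks nearest to CG9663 (1326) and CG32772 (1156) lay 965 and 1275 bp from a TSS. The peaks nearest to CG4004 (1272) and CG13323 (1232) lay 5104 and 11919 bp from it, in a non-coding exon and between genes. All 20 ranked within the first 26 of each replicate.

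CHES-1-like peaks were concentrated at promoters and nearly absent from coding sequence. Of the 4599 thresholded summits, 2895 (62.9%, 61.5 to 64.3) lay within 500 bp of a TSS, against 27.8% of the 25401 sub-threshold pooled peaks and 11.2% of random positions. The odds ratio against sub-threshold peaks was 4.41 (4.13 to 4.71). Only 9026 of the 30000 pooled entries had a deposited q-value under 0.05, all 4599 thresholded peaks among them. Most sub-threshold entries thus did not reach it and may be background, so these contrasts are not between strong and weak peaks alone. Coding sequence held 12 summits (0.261%, 0.135 to 0.455), against 11.9% of sub-threshold peaks and 13.5% of random positions (Fisher's exact test, adjusted p = 4.82e-208), and 0.609% with the best peaks of replicate 3 alone. Introns held 25.2% against 38.7%, 3' UTRs 0.565% against 2.61%, 5' UTRs 0.718% against 1.27% and intergenic sequence 9.11% against 16.2% (adjusted exact p = 1.03e-70, 8.28e-23, 0.00124 and 2.8e-38), while other exons did not differ (adjusted exact p = 0.0912). The median distance to a TSS was 182 bp for thresholded, 1602 bp for sub-threshold and 4432 bp for random positions. The promoter share was 67.7% in the 920 strongest and 58.2% in the 919 weakest peaks (Fisher's exact test, p = 2.63e-05).

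**Figure D3:**
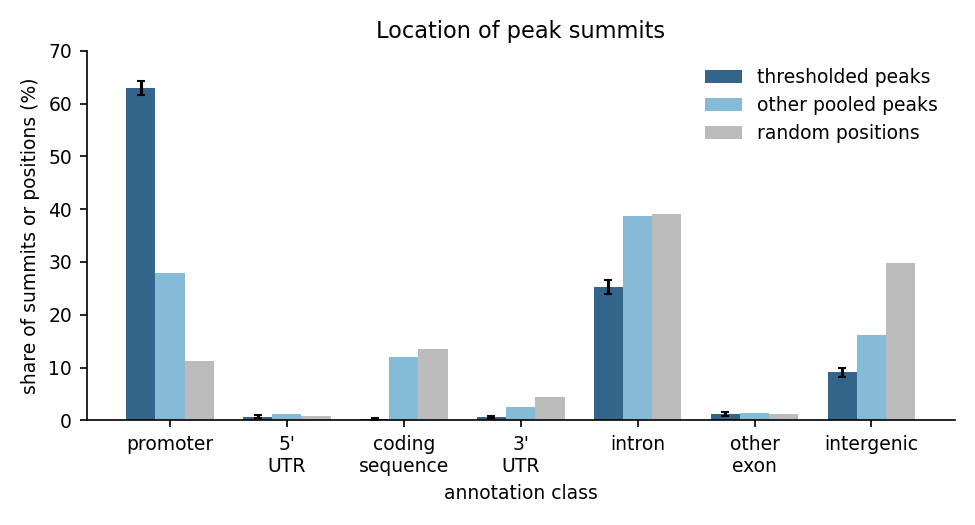
Share of thresholded summits, of the other pooled peaks and of random positions in each annotation class, in percent, with exact 95% intervals on the thresholded peaks. Promoters hold 62.9%, 27.8% and 11.2%, and coding sequence 0.261%, 11.9% and 13.5%.

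Genes for ribosomal proteins and for chromatin regulators were bound far more often than other genes. Overall 3624 of 13968 protein-coding genes (25.9%) had a thresholded summit at a TSS. Among genes for cytosolic ribosomal proteins, 69 of 92 did (75.0%, 64.9 to 83.4, odds ratio 8.71, Fisher's exact test, adjusted p = 2.5e-21), with the strongest peaks at RpL7 (signal 709), RpS27 (702), RpL14 (589) and RpL23A (554). Of the Polycomb and trithorax genes, which maintain silent and active chromatin states, 17 of 21 were bound (81.0%, odds ratio 12.2, adjusted exact p = 1.29e-06), led by ph-p (1246), Trl, which encodes GAGA factor (361), Sfmbt (211) and kis (193). Mitochondrial ribosomal protein genes were bound in 39 of 73 cases (53.4%, odds ratio 3.30, adjusted exact p = 3.11e-06), with mRpL41 (1346), mRpS10 (1212), mRpS23 (1035) and mRpL23 (640) strongest. Those 39 were all among the 60 members with another gene's TSS within 1000 bp. Of these 60, 65% were bound, against 41.3% of all genes with such a neighbour. None of the 13 others was bound, too few to decide (odds ratio 0.219, Fisher's exact test, adjusted p = 0.459). When each summit counted only for the gene of its nearest TSS, at any distance, the odds ratio of this list turned to 0.825 (adjusted exact p = 0.702). That counting gives a summit between close TSSs to only 1 gene, which lowers the bound count of close neighbours by construction. Against only genes with any pooled peak at a TSS the call of this list ended (1.54, adjusted exact p = 0.242). In that smaller set the odds ratios of the cytosolic ribosomal protein and Polycomb and trithorax lists were 4.86 and 6.71, both past the threshold, and in the 2299 strongest peaks those of the Polycomb and trithorax and mitochondrial lists were 6.28 and 2.01, both past it.

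Another 3 lists, of 13 to 39 genes, were also bound more often than other genes. Genes of the cell cycle and mitosis were bound in 20 of 39 cases (51.3%, odds ratio 3.02, adjusted exact p = 0.00254), among them Dp, the partner of E2F factors (signal 393), dup, a replication licensing gene (325), and the spindle checkpoint genes Bub3 (281) and BubR1 (205). Genes of zygotic genome activation and of chromatin pioneer and insulator proteins were bound in 8 of 13 cases (odds ratio 4.57, Fisher's exact test, adjusted p = 0.0223), with Trl (361), Dref (288), lola (281) and Cp190 (276). The JAK/STAT pathway had 8 of 14 bound genes (odds ratio 3.81, Fisher's exact test, adjusted p = 0.0366), including Su(var)2-10 (162), Stat92E, its transcription factor (140), dome, its receptor (139), and Ptp61F (133). With the best peaks of replicate 3 alone, the cell cycle and JAK/STAT calls ended (odds ratios 1.58 and 2.82, adjusted exact p = 0.295 and 0.139). With those of replicate 2 alone the zygotic activation call did (odds ratio 3.46, 0.0658), and all 3 did in the 2299 strongest peaks (odds ratios 1.97, 2.28 and 2.53, adjusted exact p = 0.244, 0.346 and 0.339) and against only genes with any pooled peak at a TSS (1.48, 4.73 and 2.36, adjusted exact p = 0.45, 0.193 and 0.371), where 8 of the 10 JAK/STAT genes left were bound. With 1 TSS per gene the JAK/STAT (odds ratio 2.38, adjusted exact p = 0.225) and zygotic activation calls (1.98, 0.285) ended, as did JAK/STAT within 1000 bp (3.28, 0.0804) and zygotic activation in peaks found in both replicates (3.55, 0.0652) and among genes without a close neighbour (3.56, 0.212), where the cell cycle (8.22) and JAK/STAT lists (7.44) passed, as zygotic activation did by the nearest TSS (38.5) and within 1000 bp (8.20).

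Cuticle protein, chemosensory and cytochrome P450 genes were seldom bound. None of 120 cuticle protein genes was bound (0%, interval up to 3.03%, adjusted exact p = 3.41e-15), nor any of 111 replication-dependent histone genes (up to 3.27%, adjusted exact p = 2.86e-14). The histone genes are near-identical copies, and 0 of the 111 had a pooled peak of any rank at a TSS, so their count of 0 cannot be read as absence of binding. Bound genes numbered 2 of 179 for odorant, gustatory and ionotropic receptors (1.12%, adjusted exact p = 1.5e-19; Ir60e and Gr63a), 2 of 51 for odorant-binding proteins (3.92%, adjusted exact p = 0.000283; Obp99b and Obp83g), and 4 of 83 for cytochrome P450 enzymes (4.82%, adjusted exact p = 3.82e-06), of which Cyp6u1 had the strongest peak (348). With the best peaks of replicate 2 alone, 3 receptor and 2 P450 genes were bound, and with those of replicate 3 alone, 1 odorant-binding protein gene and 1 cuticle protein gene, each list still past the threshold. Within 1000 bp of a TSS, 7 receptor and 2 cuticle protein genes were bound. By the nearest TSS these were 3 receptor, 5 odorant-binding protein, 7 P450 and 2 cuticle protein genes. Each list was past the threshold there too. Against only genes with any pooled peak at a TSS, the calls of the receptor (2 of 13 bound), odorant-binding protein (2 of 5) and P450 genes (4 of 22) ended (Fisher's exact test, adjusted p = 0.193, 1 and 0.0562). Among genes without a close neighbour, also a smaller set, those of the histone (0 of 27), odorant-binding protein (2 of 29) and P450 genes (3 of 69) ended (adjusted exact p = 0.0783, 0.595 and 0.0563).

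Apart from the cuticle protein genes above, tissue markers did not pass the main test in either direction. Of the tissue lists, heart and dorsal mesoderm regulators had 3 of 29 bound genes (CHES-1-like, Mef2 and polo; Fisher's exact test, adjusted p = 0.127), neural genes 4 of 31 (elav strongest, 382; adjusted exact p = 0.18), muscle structure genes 4 of 20 (Msp300, 734, and sls, 322; 0.89), blood genes 1 of 16 (ush, 174; 0.169), endoderm and gut genes 4 of 16 (fkh, 379, and bowl, 337; 1), tracheal genes 3 of 13 (bnl, 112; 1), fat body genes 2 of 15 (bmm, 157; 0.455) and germ line genes 8 of 22 (bgcn, 249; 0.407). The forkhead family had 4 of 17 (CHES-1-like, fkh, FoxK and foxo; adjusted exact p = 1), segmentation genes 4 of 28 (nanos, 190; adjusted exact p = 0.266) and the Hox genes 0 of 8 (Fisher's exact test, adjusted p = 0.19). When each summit counted for the gene of its nearest TSS, at any distance, the forkhead family was called (odds ratio 3.60, adjusted exact p = 0.0198), and the heart (odds ratio 2.26), segmentation (1.51), Hox (1.92), endoderm (1.45), tracheal (2.00) and fat body lists (1.60) turned above 1 without passing. Against only genes with any pooled peak at a TSS, the heart list was called as bound less often (odds ratio 0.196, adjusted exact p = 0.0265), as it was with peaks within 50 kb of CHES-1-like, the tagged gene, left out, an alternative chosen after seeing the data (0.211, 0.0464), and as neural genes were with a window of 250 bp (0.117, 0.0202).

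Signalling pathways other than JAK/STAT did not pass either. Their lists had bound shares between 28.6% for BMP (6 of 21) and 42.9% for DNA damage and checkpoint genes (9 of 21, adjusted exact p = 0.169), with Notch at 8 of 19 (gro, 550; 0.19), Hippo at 6 of 15 (hpo, 328; 0.309), Wnt at 11 of 28 (sgg, 497; 0.19) and insulin and TOR at 10 of 24 (Sesn, 688, and InR, 229; 0.18). Proteasome genes (20 of 48, Rpn5 strongest at 289, adjusted exact p = 0.0506), aminoacyl tRNA synthetase genes (12 of 32, 0.22) and chorion and vitelline membrane genes (0 of 14, 0.0664) missed the threshold as well. When each summit counted for the gene of its nearest TSS, the BMP (odds ratio 5.21, adjusted exact p = 0.000982), Hippo (4.80, 0.00831), Notch (3.56, 0.0161) and Wnt lists (3.20, 0.00831) were called. DNA damage genes were called with the best peaks of replicate 3 alone (odds ratio 3.11, adjusted exact p = 0.034), proteasome genes with a window of 250 bp (2.32, 0.0202) or with peaks near CHES-1-like left out (2.05, 0.0466), chorion and vitelline membrane genes with 1000 bp (0.0845, 0.0415) and insulin and TOR genes among those without a close neighbour (5.10, 0.0273).

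**Figure D4:**
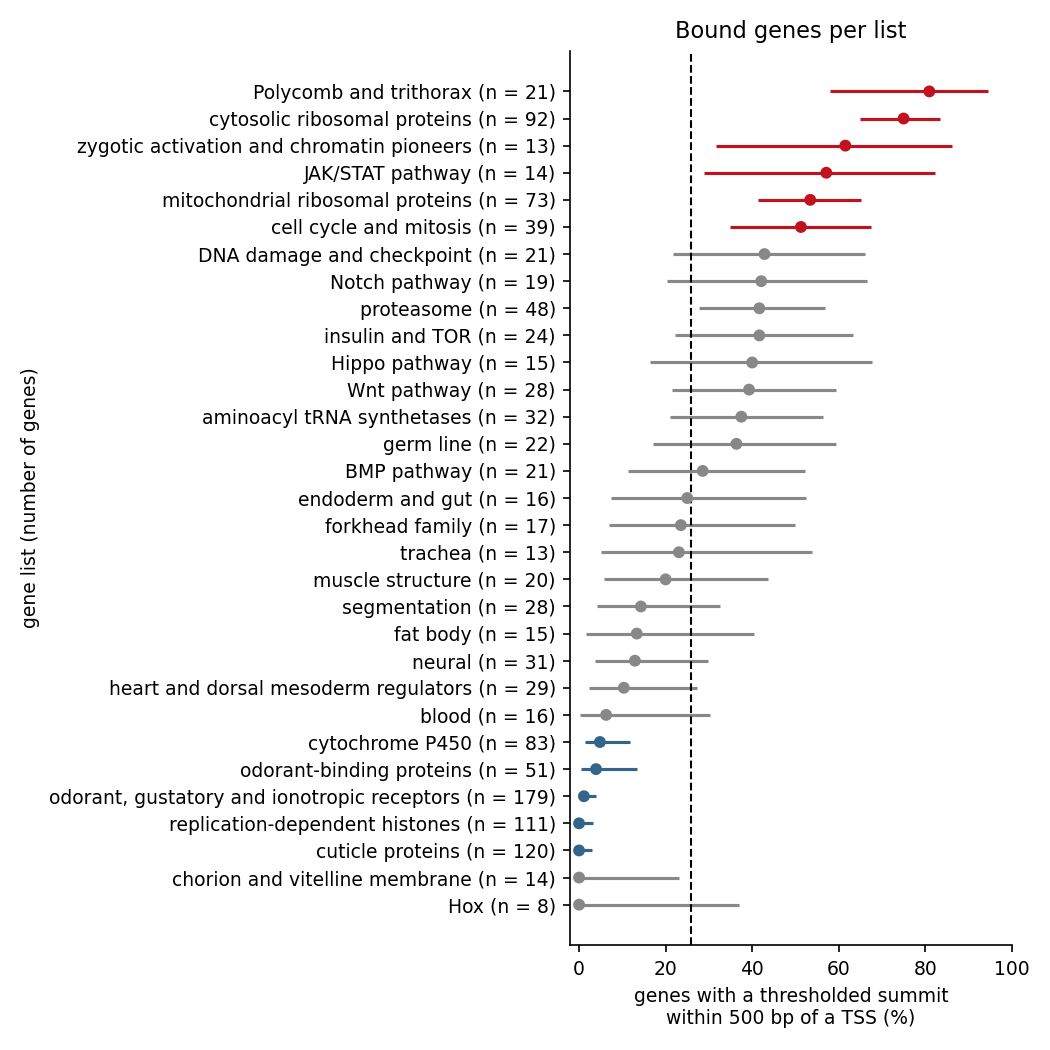
Percent of each list's genes with a thresholded summit within 500 bp of a TSS, with exact 95% intervals. The dashed line is the 25.9% of all protein-coding genes, red lists passed the test above it (6), blue lists below it (5) and grey lists did not pass (20).

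Summits were richer than their flanks in the DRE and in the Motif 1 core, both elements of promoters active in most cells. Most summits lay within 500 bp of a TSS, while flanks were centred 1000 bp away. Promoters without a peak were not scanned, so the ratios below cannot be set apart from promoter location. The DRE (TATCGATA), the site of the DREF protein, stood in 6.76% (6.05 to 7.53) of summit windows and 0.565% of flanking windows, a ratio of 11.96 (exact McNemar test, adjusted p = 1.28e-62). The core of Motif 1 (GGTCACACT), a promoter element bound by M1BP, stood in 4.26% against 0.435%, a ratio of 9.80 (adjusted exact p = 1.03e-36). Over 500 bp from any TSS, in 1704 peaks, neither the DRE (ratio 1.11) nor Motif 1 passed (adjusted exact p = 1 for both). Against shuffled sequence the ratios were 31.1 and 49.0, with windows of 250 bp 6.85 for both, at summits near TSSs 15.1 and 21.4, and for Motif 1 in peaks found in both replicates 15.6.

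The forkhead site was more frequent at summits, and so was its reversed control, to a degree that the test did not tell apart. The site (RYAAACA) stood in 29.4% against 22.2%, a ratio of 1.32 (adjusted exact p = 4.82e-14), and its reversed control in 26.0% against 20.6%, a ratio of 1.27 (adjusted exact p = 2.81e-09). The quotient of these ratios was 1.04, with a bootstrap interval of 0.954 to 1.13. Site and control share the word ACAAACA, which draws the quotient towards 1. Without it in either, a test chosen after seeing the data, the quotient was 1.05 (0.932 to 1.19). The GACGC site was less frequent at summits, 16.1% against 19.9% (adjusted exact p = 4.62e-06), as was its reversed control, 26.7% against 30.5% (adjusted exact p = 0.000196). GC content was 39.5% at summits and 43.7% in flanks. With flanks matched in GC content, an alternative chosen after seeing the data, neither the GACGC site (ratio 1.05, adjusted exact p = 0.385) nor its control (1.05, 0.187) passed, while the forkhead site (1.15, 0.000157) and its control (1.11, 0.00815) did with smaller ratios, and neither GACGC form passed with windows of 250 bp (0.971, 0.315 and 0.993, 0.766). The control's call also ended with the best peaks of replicate 3 alone (0.935, 0.062) and over 500 bp from any TSS (0.878, 0.109), and turned against shuffled sequence (1.14, 0.000228).

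Of the other sites, 3 passed the test between summits and flanks. The GAGA site (4.54% against 3.35%, adjusted exact p = 0.0072) and the E-box CAGCTG (12.7% against 11.2%, adjusted exact p = 0.0458) were more frequent at summits, the Zelda site less (0.891% against 1.41%, adjusted exact p = 0.0375). GAGA matches were not densest at the summit itself. They stood at 0.235 and 0.274 per kb within 50 bp on its left and right, against 0.544 and 0.522 at 150 to 200 bp. The E-box CACGTG, the GATA site and the Grainyhead site did not pass (adjusted exact p = 0.176, 0.171 and 0.585). With the best peaks of replicate 2 alone the GAGA and CAGCTG calls ended (ratio 1.13 for both, adjusted exact p = 0.306 and 0.0535), with those of replicate 3 alone the Zelda call did (0.769, 0.302), and all 3 did with windows of 50 bp (0.626, 0.183 and 0.32), in the 2299 strongest peaks (0.548, 0.684 and 0.18) and over 500 bp from any TSS (0.753, 0.435 and 1), as GAGA did in peaks found in both replicates (1.18, 0.178) and with flanks 500 bp away, where it turned (0.968, 0.829). With flanks matched in GC content, Zelda did not pass (1.02, 1) while GATA (0.673, 0.00245) and CACGTG (1.41, 0.0163) passed, as CACGTG did with windows of 250 bp (1.24, 0.00946). Against shuffled sequence GAGA (3.94) and CAGCTG (3.39) passed with larger ratios while Zelda turned without passing (1.21, 0.579).

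No motif differed between the strongest and weakest 5th of peaks after adjustment. The forkhead site stood in 27.0% and 32.2% of them (Fisher's exact test, adjusted p = 0.0853). Ordered by rank in replicate 3 it passed (odds ratio 0.729, adjusted exact p = 0.0325), and Motif 1 did by rank in replicate 2 (0.389, 0.0127) and within the 2299 strongest peaks (0.293, 0.0341).

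**Figure D5:**
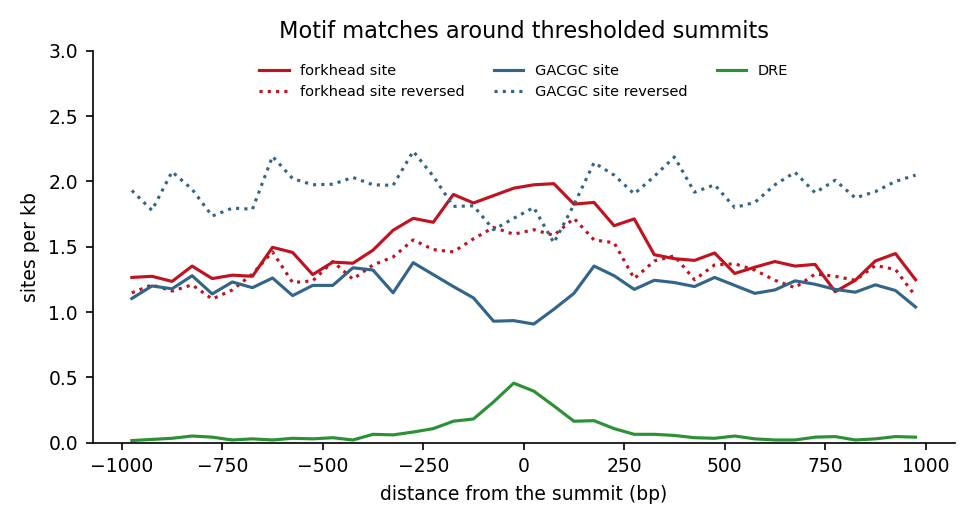
Matches per kb of sequence by distance from the thresholded summits, in bins of 50 bp, for the forkhead and GACGC sites, their reversed controls (dotted) and the DRE. The DRE peaks at 0.457 sites per kb beside the summit, and the forkhead site and its control both rise.

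Along the chromosomes, peaks were sparse on the small chromosome 4, and the large arms lay between 1.00 and 1.09 times the number their length gave. Chromosome 4 held 16 thresholded peaks where its length gave 45.1 (ratio 0.355, exact binomial test, adjusted p = 3.31e-06), although it held 0.968% of sub-threshold peaks and 0.98% of the genome. Arm 2L held 858 peaks (ratio 1.09, adjusted exact p = 0.0126). When the expected number came from the genes per arm, with 1 TSS per gene, chromosome 4 (0.607, adjusted exact p = 0.0786) and 2L (0.981, 0.535) no longer passed. Arm X then passed (1.10, 0.0205). The 2L call also ended with the best peaks of replicate 3 alone (1.06, 0.142), where 2R passed (1.11, 0.000958), in the 2299 strongest peaks (1.09, 0.086), against sub-threshold peaks (0.991, 0.777) and, an alternative chosen after seeing the data, over arms that hold pooled peaks (1.06, 0.158). Arms 2R (902), 3L (956), 3R (1075) and X (792) did not pass, with ratios between 1.00 and 1.07. No list held a peak on Y, so its ratio of 0 says nothing of binding. The dm3 and dm6 thresholded lists held 4633 and 4599 peaks, 797 and 792 of them on X.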

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

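The dm3 pooled list held 34 peaks on scaffolds outside the major arms. They are noted because they lie in data that no comparison uses. The best of them, on 3LHet, ranked 6550, so none reached the thresholded list. Scaffold XHet held 10 of them and 3LHet 10.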

How the results depend on the processing

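Tests leaving out peaks within 50 kb of CHES-1-like, taking arms that hold pooled peaks, matching flanks in GC content and leaving out the word shared by the forkhead site and its control were chosen only after the result was seen, and the cause of the changes was not tested except where stated. Of 648 values recomputed under the alternatives, 493 kept their direction and side of the threshold or stayed within their interval or 1.5 times a count. The depth is unknown and its limit was not tested. The replicate overlap of 68.9% was 77.3% by 1 bp of overlap, 76.5% by summits within 250 bp, 74.1% with the best 2299 peaks, 76.6% in the best 1000 and 42.6% in whole lists. The share of thresholded peaks in both replicates was 99.9% by 1 bp, 90.2% by 50% reciprocal overlap, 99.5% within 250 bp and 97.5% in the 2299 strongest, and the rank correlation within 250 bp was 0.678. The promoter share lay between 61.8% and 64.1% without replicate 3 or 2, and the coding share between 0.283% and 0.609%. Either replicate alone gave 3 arms, 5 lists bound more and 5 bound less often, and 4 to 6 motifs higher at summits. Lists bound more often numbered 3 in the 2299 strongest, 2 against genes with a pooled peak and 10 by the nearest TSS, against 6, and lists bound less often 2 against genes with a pooled peak and 2 among genes without a close neighbour, against 5; both backgrounds hold fewer genes. Motifs higher at summits numbered 2 away from TSSs, against 6. Motifs differing with strength numbered 1 in the 2299 strongest, by rank in replicate 2 and by rank in replicate 3, against 0. Arms past the threshold numbered 1 with sub-threshold peaks as expectation, in dm6 and in dm3, and 1 over arms that hold pooled peaks, against 3; Y then leaves the test. For dm3 no arm lengths were used, so sub-threshold peaks gave the expectation. Of the single values, 71 changed direction. Ratios of arms did so in the 2299 strongest (3L 0.962, X 0.991), without replicate 3 (3L 0.993) and without replicate 2 (X 0.967, while 3L was 1.00). They did so in peaks found in both replicates (3R 0.996) and against genes per arm, with 1 TSS per gene (2L 0.981, 2R 0.961, 3R 0.954). The same held against sub-threshold peaks (2L 0.991, 3L 0.940), in dm3 (2L 0.995, 3L 0.947) and over arms that hold pooled peaks (3L 0.990, 3R 0.976, X 0.979). Odds ratios of lists did so with a window of 250 bp (forkhead 1.08, endoderm 1.18) or 1000 bp (forkhead 1.02), with 1 TSS per gene (BMP 0.991), in the 2299 strongest (forkhead 1.22, Wnt 0.948, BMP 0.948), without replicate 2 (forkhead 1.17, endoderm 1.28; 0.635 and 0.423 without replicate 3) and in peaks found in both replicates (endoderm 1.01). They also did so against genes with a pooled peak (forkhead 1.18, Wnt 0.927, BMP 0.589, tRNA synthetases 0.944), by the nearest TSS (forkhead 3.60, heart 2.26, segmentation 1.51, Hox 1.92, endoderm 1.45, trachea 2.00, fat body 1.60, mitochondrial ribosomal 0.825) and without close neighbours (forkhead 1.37, muscle 1.19, BMP 0.988, endoderm 2.16, trachea 1.78, mitochondrial ribosomal 0.219, tRNA synthetases 0.348). Ratios of motifs did so in windows of 50 bp (Grainyhead 0.444), against shuffled sequence (GACGC reversed 1.14, Zelda 1.21, CACGTG 0.910, GATA 1.07, Grainyhead 0.944), with flanks at 500 bp (GAGA 0.968) and away from TSSs (Zelda 1.05, CAGCTG 0.859, GATA 1.24, Grainyhead 0.857). Grainyhead also did so in the 2299 strongest (0.444), without replicate 3 (0.944), without replicate 2 (0.769) and in peaks found in both replicates (0.882). With flanks matched in GC content, GACGC 1.05, its reversed control 1.05, Zelda 1.02 and Grainyhead 0.895 did so. Odds ratios of strongest against weakest peaks did so in the 2299 strongest (forkhead 1.12, its reversed control 1.15, GACGC 1.17, GAGA 1.37, DRE 0.611, Zelda 1.67, CACGTG 0.861, GATA 1.22). Of all single values, those that changed direction included, 21 came to pass the threshold and 54 no longer passed it.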

Other observations

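The counts per gene, the comparison of neighbouring genes, the search for short words, the count of lists with 1 TSS per gene, the adjustment of the logistic model over all lists, the division of tRNA genes by sequence copies, the forkhead test without the shared word and both tests on the cluster in CHES-1-like were chosen only after the result was seen. Several genes carried many thresholded peaks. After CHES-1-like, with 14 summits in 27.0 kb, ush followed with 13 in 64.3 kb and CG1677 with 12 in 125 kb. kirre held 11 in 394 kb and shn 11 in 58.3 kb. Raf, Tlk and tara held 10 each, in 48.4, 69.8 and 34.7 kb. shn encodes a zinc finger protein of BMP signalling, Raf and Tlk protein kinases, and Eip75B, with 8 in 114 kb, an ecdysone-induced nuclear receptor. HmgD and HmgZ, overlapping genes for high mobility group proteins, held 7 each in 15.3 and 10.4 kb.

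Genes with a close neighbour were bound more often. Of the 5985 protein-coding genes with another gene's TSS within 1000 bp, 41.3% were bound, against 14.4% of the 7983 others (odds ratio 4.17, Fisher's exact test, p = 4.73e-282). A summit between close TSSs counts for both genes, which raises the first share by construction. Cytosolic ribosomal protein genes were bound in 84.5% of 58 members with such a neighbour and in 58.8% of 34 without.

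Words of 7 bases were ranked in every other peak and tested in the rest. ATCGATA, which lies within the DRE, stood in 13.7% of the 2299 test windows and 2.65% of their flanks (exact McNemar test, adjusted p = 6.55e-44). AGTGTTG stood in 8.13% against 2.70% (adjusted exact p = 5.67e-16). In the 920 strongest peaks, ACAGTGG stood in 10.4% of 460 test windows against 2.17% (adjusted exact p = 3.24e-07), and CACAGTG in 9.35% against 2.83% (adjusted exact p = 9.07e-05). Of the 10 words ranked highest there, 9 passed in the test peaks. Most of the 10 were rich in A and T, led by TTAAAAA (20.2% against 10.7%). Flanks were matched neither in GC content nor in distance to a TSS in this search, and GC content was lower at summits. ACAGTGG and CACAGTG overlap in sequence, so they are not separate findings.

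The matched share of the best peaks was 63.3 percentage points higher in the strongest than in the weakest 5th of replicate 2. Both lists end at the same rank, which lowers the share in the weakest 5th by construction.

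Promoters held most peaks, and 6 gene lists were bound more often than other genes. If strong transcription alone raised recovery, tRNA genes should be bound at least as often as protein-coding genes, but 15 of 290 were (5.17%, 2.92 to 8.39) against 25.9%, and 7.28% (4.13 to 11.7) of the 206 with at least 90% of the words of 31 bases around them found once in the arms. Both upper bounds lie below 25.9%, which argues against the explanation for tRNA genes only, and only so far as they are strongly transcribed. Their transcription was not measured. The words were taken from 500 bp on each side of the start, so a tRNA gene repeated elsewhere could still pass. Peaks of any rank stood at 45.2% of tRNA and 56.6% of protein-coding genes. The 75.0% of cytosolic ribosomal protein genes bound, against 0% of cuticle protein genes, go with the explanation, but they are part of the pattern it is meant to explain. No transcript levels were measured here, so it stays open for protein-coding genes. In a logistic model of 13968 genes with their number of TSSs as a covariate, all 6 lists stayed past an unadjusted 0.05. After adjustment over 31 lists JAK/STAT (odds ratio 3.49, 1.18 to 10.3, Wald test, 0.0575) and zygotic activation (3.70, 1.16 to 11.9, 0.0609) did not. With 1 TSS per gene 4 lists passed, but neither of these (Fisher's exact test, 0.225 and 0.285), so TSS number stays open for both. Some lists not called in the main test came to pass in the adjusted model. Proteasome genes, with 20 of 48 bound, did so (Wald test, 0.0208). Hox genes, with 0 of 8 bound, passed as bound less often (likelihood ratio test, 0.0193). So did chorion and vitelline membrane genes, with 0 of 14 bound (likelihood ratio test, 0.0258). Open promoter chromatin and the antibody itself stay open, since no mock sample is analysed here, and no biological explanation was tested.

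The forkhead site was enriched at summits, but its ratio was 1.04 times that of its reversed control (bootstrap interval 0.954 to 1.13). Site and control share a word, and without it the quotient was 1.05 (0.932 to 1.19). Recovery of open chromatin whatever its sequence may give these values, as may recruitment through other factors, which was not tested. Chromatin accessibility was not measured. GC content was 39.5% at summits and 43.7% in flanks. With flanks matched in GC content the ratios of site and control were both smaller, as given above, so base composition is not set apart from these explanations. For the GACGC site the quotient was 0.923 (0.837 to 1.01), which decides nothing, since the site was not enriched at summits. No biological explanation was tested.

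CHES-1-like, a gene named before the data were examined, held 14 thresholded summits. The highest of 427 genes within 25% of its length held 7 (median 0), so 0% held as many (upper bound 0.86%) and length alone does not account for the cluster. If extra copies of the gene raised coverage evenly, summits should also fall in its coding sequence, which is 14.1% of its length. None of 14 did where 1.97 would be expected (exact one-sided binomial p = 0.12), too few to decide. The labels speak of transgenic flies and neither state nor exclude extra copies of the gene. Peaks multiplied by extra copies and binding of the protein to its own gene both stay open as hypotheses.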
